A study of Mus musculus with 3 samples.

How the data were processed

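The series holds 3 libraries from mouse embryonic stem (ES) cells of the J1 line that carry a transgene for Tex10 with a FLAG epitope tag: a chromatin immunoprecipitation with an antibody against FLAG, a control immunoprecipitation with normal mouse IgG, and the input DNA. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA bound by, or lying close to, a protein. The 3 libraries were assigned to 3 groups of 1 by the antibody or the sample title. A processed file was used for 1 of them, the FLAG library. The IgG and input libraries were not analysed here as separate measurements, and whether either served as the control for peak calling is not given in the sources used here.

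The file is a list of peaks, each with a chromosome, a start, an end, a peak name and a number. The number is treated here as a score, as the authors deposited it, since no header names it. The lowest score, 1.31, lies just above 1.30, which is −log10 of 0.05, and many scores recur exactly. Both properties are those of a −log10 q-value from a peak caller such as MACS, but neither the caller nor the scale is given in the sources used here, so scores were used only to rank peaks, to filter them within this list and to find exactly repeated values. Per the submitters' processing notes the genome build was mm9, and FastQC 0.10.1, Bowtie 1.0.0, SAMtools 0.1.19 and bedtools 2.18.1 were used, with no role or order stated. The mm9 chromosome lengths were taken from the GenomeInfoDb package, version 1.38.1, under R 4.3.3. Of the peaks, 0 ran past the end of their mm9 chromosome. Starts are given 1-based.

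The list holds no read counts, so the sequencing depth and the coverage behind a peak are unknown, and no interval that needs them is given. With 1 immunoprecipitation and no replicate, every p-value describes how the peaks of this one list are arranged, and not the spread between experiments. Peaks were necessarily called on 1 ChIP library. A list of peaks past a threshold also depends on depth: a region read more deeply yields more peaks at the same enrichment.

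The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks per chromosome were compared with the chromosome's share of total length over 21 chromosomes (19 autosomes, X and Y) by a two-sided exact binomial test with Benjamini-Hochberg adjustment. Assembly gaps were left in the lengths, since no mm9 sequence was used. The 95% intervals of peaks per Mb came from 10000 bootstrap draws of 5 Mb bins. Because neighbouring peaks are not independent, full 5 Mb bins were also permuted 100000 times between each chromosome and the autosomes (two-sided). Bins were drawn and moved singly, without allowance for likeness between neighbouring bins. The bootstrap intervals may therefore be too narrow and the permutation p-values too small. Peaks less than 12.5 kb apart were joined into stretches, and the number of stretches of at least 3 peaks was compared with 1000 random placements of peaks of the same widths on the same chromosomes (one-sided for an excess). Scores of peaks inside and outside such stretches were compared by a two-sided rank test with 100000 permutations. The named peaks are the 10 with the highest scores, and the named stretches are the 5 with the most peaks, with ties broken by covered length. Regions outside this rule were chosen after their values were seen, and the text says so. The binomial and placement tests, this rule and part of the alternative settings were fixed before the data were examined. The rank test was fixed for clustered against single peaks, but was run against all other peaks, pairs included. The bin permutation, the expectations by gene number, the lengths from first to last peak, the division of autosomes at their midpoint, the removal of the densest or strongest stretches and the counting of pairs as clustered were chosen after.

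The scripts were tested on simulated peak lists of 5187 peaks, with 20 lists per setting. With peak rates of chromosome 8 raised and of chromosome X lowered, and 100 stretches planted, both chromosomes were called in 20 of 20 lists, the clustering was called in 20 of 20, and the mean excess of stretches was 99.9. In those lists chromosomes with an unaltered rate were called 13 times over all 20. A raised or lowered chromosome moves the expected share of the others, and peaks of a planted stretch are not independent. Which of these led to the calls was not tested. In unchanged lists chromosome 8 was called above and X below its expected share in 0 of 20, and calls of these chromosomes in the other direction were not counted. Other chromosomes were called 3 times over all 20 lists, and the clustering in 2 of 20.

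The planned comparisons of peaks with promoters, gene lists, sequence motifs and the exons of Tex10, and the nearest gene of each named peak, were not made. The gene table used here belongs to another build (RefSeq genes of GRCm38.p6), and coordinates of the 2 builds are not interchangeable. That table served only for the number of protein-coding genes on each chromosome. For the same reason no values are given for Tex10, Pou5f1, Sox2, Nanog, Klf4 or Esrrb, and no peak is assigned to a gene.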

Results

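Tex10 was mapped on chromatin in mouse ES cells, which are pluripotent cells of the early embryo kept in culture, here with serum and leukaemia inhibitory factor. The protein carried a FLAG tag and was expressed from a transposon-borne transgene in J1 cells, a line of 129 background. The series title places Tex10 in the control of super-enhancers, which are dense groups of enhancers next to genes of cell identity, in pluripotency and reprogramming. The deposited list for the FLAG library held 5189 peaks, with no replicate, and its depth is unknown. The comparisons that it allows are where the peaks lie, how they are grouped and how their scores differ.

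The peaks were short and few. Their median width was 314 bp, with quartiles of 253 and 402 bp. Together they covered 1846 kb, or 0.070% of the assembled mm9 chromosomes. The narrowest width, 224 bp, was shared by 606 peaks (11.7%). The median score was 5.22, with quartiles of 3.75 and 7.73, and 752 peaks (14.5%) had a score of at least 10. A small set stood far above the rest: 34 peaks scored at least 100 and 10 scored at least 200, up to 432. Wider peaks tended to score higher, with a Spearman correlation of 0.37 across peaks, which are not independent replicates.

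**Figure D1:**
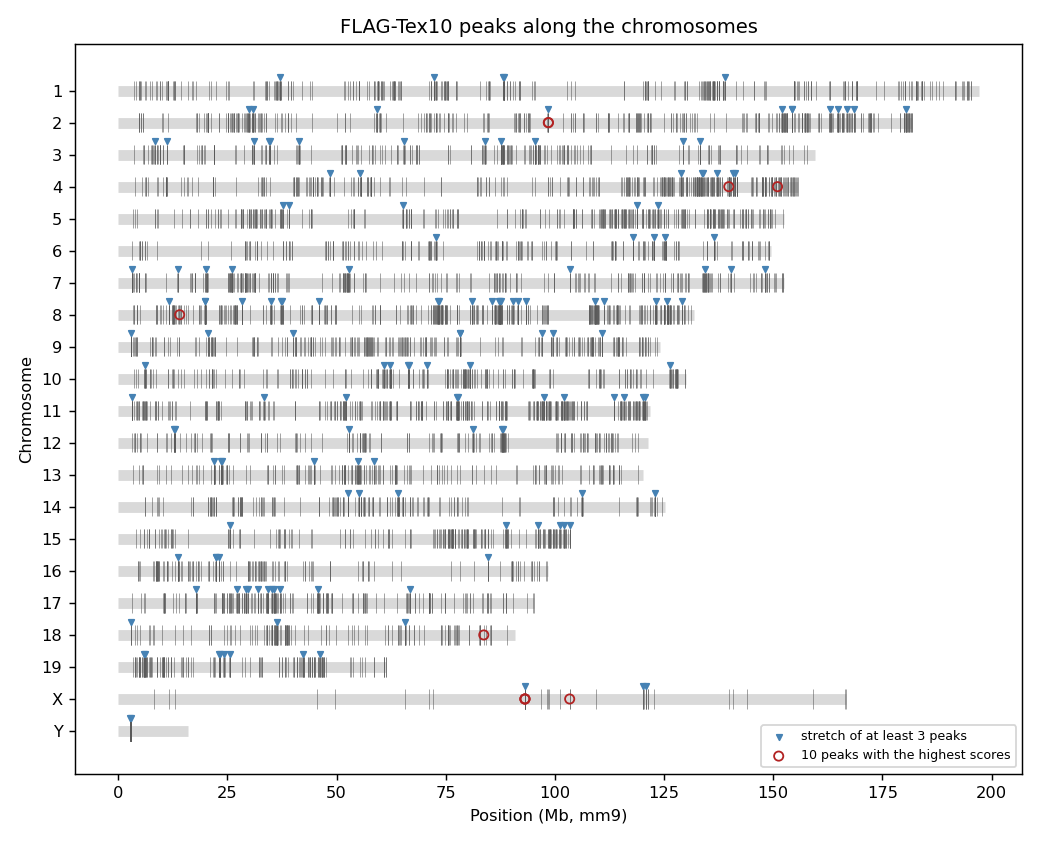
Position in Mb (mm9) of every FLAG-Tex10 peak (dark ticks) along the 19 autosomes, X and Y (grey bars to scale). Triangles mark the 161 stretches of at least 3 peaks and open circles the 10 peaks with the highest scores, of which 4 lie on X although X carries 40 peaks.

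The 10 strongest peaks lay on 5 chromosomes, and 5 of them shared a stretch with another of the 10. Chromosome X held 4 of the 10 highest-scoring peaks. The highest of all, with a score of 432, lay at chromosome X 93135524 to 93136397. Peaks scoring 285 (93147128 to 93147648) and 218 (93141646 to 93142533) lay in the same stretch of X. The second-highest, scoring 333, was also on X, at 103381946 to 103382684. Chromosome 4 carried peaks scoring 317 (139814792 to 139815446) and 228 (150978580 to 150979434). A peak scoring 302 lay on chromosome 18 at 83712715 to 83713886. Chromosome 2 carried 2 of the 10 within 1 stretch, scoring 252 (98506288 to 98507590) and 211 (98502290 to 98503225). The last of the 10, with a score of 204, lay on chromosome 8 at 14072451 to 14072968. No control value per peak was used, so these scores were not set against the IgG or input libraries. Whether DNA of the transgene contributed to any of these peaks was not tested.

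The mitochondrial genome carried 2 peaks of unusual width, 6439 bp (39 to 6477, score 33.2) and 5334 bp (10950 to 16283, score 93.6), which together covered 72.2% of it. The only other peak wider than 2 kb, chosen after its values were seen, spanned 5964 bp on chromosome 17 (39979874 to 39985837) and scored 125.

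The first comparison asked whether peaks gathered on particular chromosomes. Chromosome 8 carried the most peaks for its length, 443 peaks or 3.36 per Mb (95% bootstrap interval 2.51 to 4.27), which was 1.72 times the number expected from length. Chromosome 11 followed with 387 peaks, 3.18 per Mb (2.34 to 4.07) and 1.63 times the expected number, but it had 1.01 times the number expected from its protein-coding genes (exact binomial test, adjusted p = 0.75). Chromosome X carried 40 peaks, 0.24 per Mb (0.11 to 0.41), or 0.12 times the expected number. The autosomes together had 2.07 peaks per Mb, 8.63 times the density of X, and single autosomes ranged from 1.49 on chromosome 18 to 3.36 on chromosome 8.

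By the exact binomial test, 7 chromosomes lay above and 8 below the share set by their length at an adjusted p under 0.05, and 6 were not called. By this exact test the adjusted p was 2.7e-26 for chromosome 8, 5.7e-19 for chromosome 11 and 2.4e-91 for X. When 5 Mb bins were permuted, which allows for peaks that lie together within a bin, 3 of 20 chromosomes were called (Y has too few bins). By this permutation the adjusted p was 0.0011 for chromosome 8, 0.025 for chromosome 11 and 0.0002 for X. Likeness between neighbouring bins was not allowed for, so these p-values may be too small. Chromosome 19 (1.43 times the expected number) and chromosome 4 (1.23 times) were called by the binomial test but not by the permutation of bins (adjusted p = 0.41 and 0.44), and so was chromosome 18 on the low side (0.76 times, adjusted p = 0.41).

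The density on chromosome 8 was uneven along its length. Up to the midpoint it held 159 peaks, 2.41 per Mb or 1.24 times the number expected from length, and beyond it 284 peaks, 4.31 per Mb or 2.21 times, so most of the excess lay in the distal part. Of the 38 parts made by dividing each autosome at its midpoint, the distal part of chromosome 8 was the densest and the proximal part ranked 10. Its median 5 Mb bin held 14.5 peaks, against 7 for the bins of the other autosomes, and 1 of its 26 full bins was empty. On X, 20 of 33 full bins were empty and 2 bins held 18 of the 40 peaks. Chromosome Y carried 27 peaks, all within the first 2.90 Mb, and its density of 1.70 per Mb (0 to 4.57) was not distinguishable from the share set by its length (adjusted p = 0.58, exact binomial test). That comparison depends on the length used, since assembly gaps were left in. Measured from its first to its last peak Y had 54.4 times the expected number (exact binomial test, adjusted p = 3.4e-36), a span that the peaks themselves set. By its number of protein-coding genes it had 0.45 times (exact binomial test, adjusted p = 1.1e-05). Those genes were counted in another build (GRCm38.p6), so this deficit cannot be told apart from a difference between builds.

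Chromosome 8 also differed in its scores. Across the list, 5 scores (3.25, 4.05, 4.91, 5.82 and 6.76) recurred exactly in at least 90 peaks each, 573 peaks in all. The cutoff of 90 peaks was not among the settings fixed before the data were examined, and results at other cutoffs are not given. On chromosome 8, 7 of 443 peaks (1.58%) had one of these scores, whereas the share on the other 18 autosomes ranged from 7.24% on chromosome 11 to 22.9% on chromosome 3. The odds ratio of chromosome 8 against the other autosomes was 0.12 (95% interval 0.047 to 0.25, Fisher's exact test, two-sided, p = 2.7e-15). Fisher's test treats peaks as independent, so this p-value may be too small. On X the share was 20.0% (8 of 40), which did not differ detectably from the 11.04% of the autosomes (odds ratio 2.02, interval 0.80 to 4.49, Fisher's exact test, two-sided, p = 0.078). On Y, 0 of 27 peaks had one of these scores, which allows a share of up to 11.1%.

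**Figure D2:**
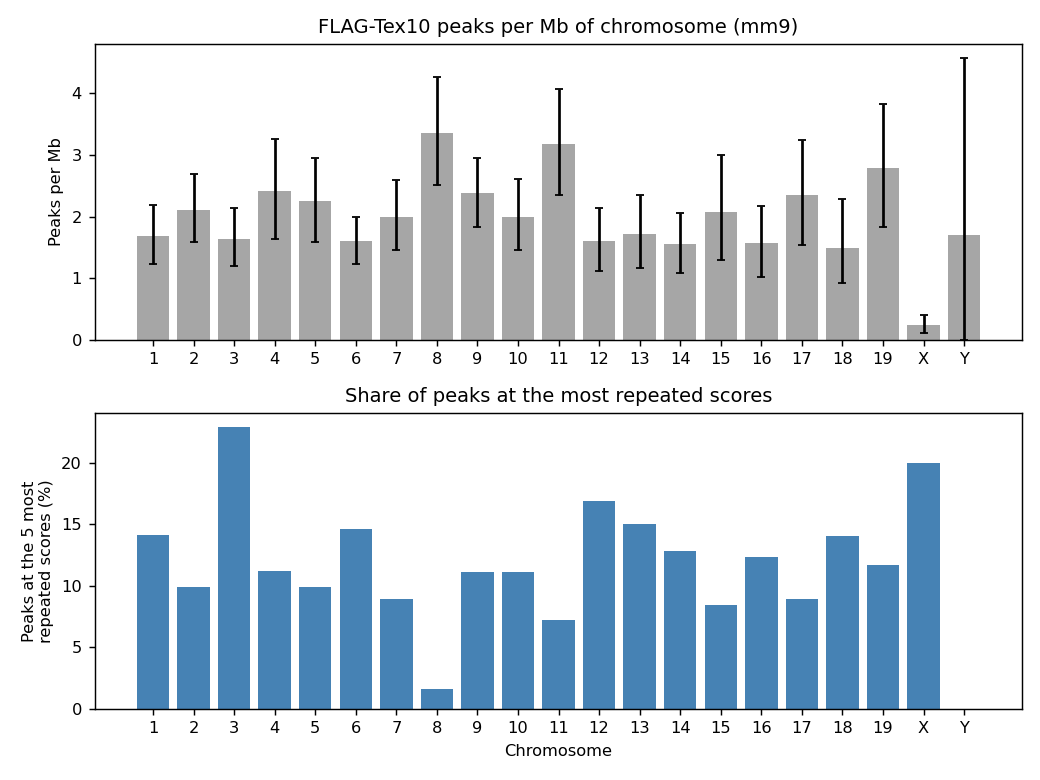
Upper panel: peaks per Mb (bars) for each chromosome with 95% bootstrap intervals over 5 Mb bins (lines). Lower panel: percent of each chromosome's peaks that have one of the 5 most repeated scores. Chromosome 8 has the highest density (3.36 per Mb) and the lowest share among the autosomes (1.58%), and X has the lowest density (0.24 per Mb).

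The second comparison asked whether the peaks formed groups, as enhancer clusters would. Joining neighbouring peaks left 4274 stretches, of which 3643 were single peaks (70.2% of the peaks on the autosomes, X and Y) and 470 were pairs. The remaining 161 stretches held at least 3 peaks and 604 peaks in all (11.6%). Their median length was 8.89 kb and the longest was 42.1 kb. Each of the 21 chromosomes had at least 2 of them, and chromosome 8 had the most, with 23 stretches that held 92 of its peaks (20.8%).

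Random placement on the same chromosomes gave a mean of 3.98 such stretches and at most 12 in 1000 placements, so the observed 161 exceeded chance by 40.5 times (permutation p = 0.001, the smallest that 1000 placements can give). Placing each peak at random within 100 kb of its position, which keeps the regional density, gave a mean of 57.8 and at most 82, and the excess was 2.79 times (permutation p = 0.001).

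**Figure D3:**
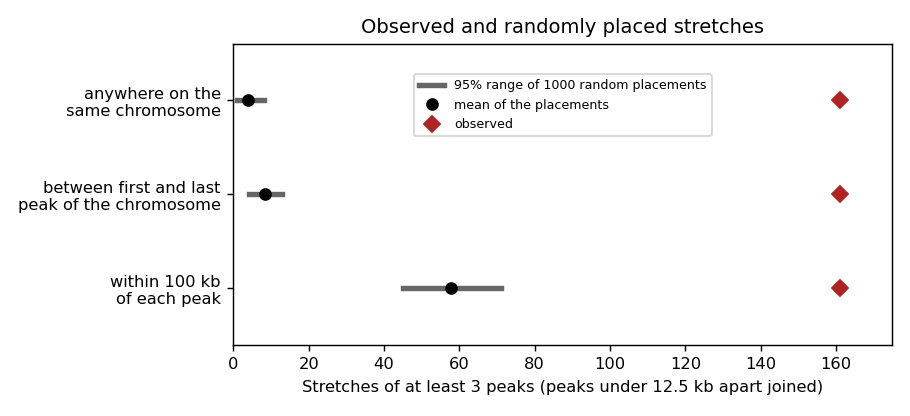
Number of stretches of at least 3 peaks on the x axis for the deposited peaks (diamonds, 161) and for 1000 random placements (dots, mean; bars, 95% range) under 3 ways of placing peaks. The observed number lies above every range, including that of placement within 100 kb, whose mean is 57.8.

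The stretch with the most peaks lay near the start of chromosome 9 (2999953 to 3038171), with 19 peaks that covered 27.8% of its 38.2 kb and a highest score of 131. The next held 18 peaks over 42.1 kb of chromosome Y (2853987 to 2896041), with scores of up to 13.9. A stretch of 26.5 kb on chromosome 8 (19921556 to 19948073) held 10 peaks with scores of up to 11.8. The stretch of chromosome X with the highest-scoring peak (93130748 to 93152308) held 8 peaks with a median score of 126. A stretch of chromosome 7 (3193483 to 3219224) also held 8 peaks, with a median score of 7.33. On chromosome Y, 26 of the 27 peaks lay in 2 stretches.

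Peaks inside stretches of at least 3 scored slightly higher than the others, a difference that depended on how clustered peaks were defined. The median score was 5.54 for the 604 clustered peaks and 5.07 for the other 4583, which include pairs. A clustered peak outranked another peak with a probability of 0.53 (rank test with 100000 permutations, two-sided, p = 0.0073). Single peaks alone, the comparison fixed beforehand, had a median score of 5.15, and clustered peaks were not ranked against them alone. Without X, Y and the densest or strongest stretches, which are those with at least 8 peaks or a score of at least 100, the probability was 0.51 (permutation p = 0.31), a removal that itself uses the score. With pairs also counted as clustered the probability was 0.4996 (permutation p = 0.97). Clustered peaks were also wider, with a median of 334.5 bp against 311 bp (probability 0.56, permutation p = 1e-05, the smallest that 100000 permutations can give). Widths were not compared without the densest or strongest stretches. The permutations of score and width moved single peaks and made no allowance for likeness within a stretch, so their p-values may be too small. Among the 100 highest-scoring peaks of the autosomes, X and Y, 69 were single and 20 lay in stretches of at least 3. Of all peaks on these chromosomes, 70.2% were single and 11.6% lay in such stretches.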

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

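The direction and the call of the clustering held under all 9 alternatives, 6 of them planned, with an excess over random placement of 2.79 times (placement within 100 kb) or more. With at least 5 peaks per stretch, 20 were observed and at most 1 at random. The excess on chromosome 8 kept its direction and call under 7 alternatives (1.62 to 1.80 times the expected number) and the deficit on X under 6 (0.12 to 0.17 times). The number of chromosomes called depended on the setting, and was 15 by length. In planned settings it was 15 with peaks under 500 bp apart joined, 13 without X and Y and 10 with only the peaks above the median score. It was 8 when the expectation came from the number of protein-coding genes and 4 when olfactory and vomeronasal receptor genes were left out of that number. It was 3 when bins were permuted and 16 by lengths from first to last peak. The settings by genes, by bins and by first to last peak were chosen after seeing the data. Under the gene-based expectations (all genes, then without receptors) some chromosomes changed sides. Chromosome 1 went from a called deficit of 0.86 to 1.16 (called, exact binomial test, adjusted p = 0.019) and 1.11 times the expected number, and chromosome 12 from 0.82 to 1.21 (called, adjusted p = 0.024) and 1.13 times. Chromosome 7, at 1.02 times by length and not called, became a called deficit of 0.63 (adjusted p = 9.9e-19) and 0.74 times (adjusted p = 8.5e-08, all exact binomial tests), and without X and Y or from first to last peak it was at 0.959 and 0.998 times, not called. Chromosomes 3 and 17 also changed sides and were then not called. Chromosome Y, not called by length, was a called deficit by genes (0.45 and 0.42 times) and a called excess from its first to its last peak (54.4 times). Its genes were counted in another build than its peaks, so the deficit by genes cannot be told apart from a difference between builds. Chromosome 11 changed from an excess to 1.01 and, without receptors, 0.998 times the expected number, and chromosome 18 from a deficit to 1.11 and 1.04 times, and neither was then called. That the expectation by genes removed the call of chromosome 11 follows from its gene number. The higher score of clustered peaks did not hold without X, Y and the densest or strongest stretches (probability 0.514, with regions removed partly by their score) and changed direction when pairs were counted as clustered (0.4996, permutation p = 0.97). The cause of the second was not tested. Joining peaks under 500 bp apart left 4979 peaks. No paired analysis was possible because each group has 1 library and the values come from 1 list. Alternatives that needed promoters, genes or sequence on mm9 were not run. Depth limits the list itself, since peaks below its threshold are not in it.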

Other observations

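The tests in this part were chosen after the results were seen, with some exceptions. The placement of all peaks within 100 kb was planned, and its prediction was written before its value was known. The odds ratios of repeated scores on chromosomes 8 and X were not planned and address an excess and a deficit already seen. Only their predictions were written before their values were known. The count of stretches after joining peaks under 500 bp apart was also planned.

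Peak density followed gene density across the autosomes. Over 19 autosomes, peaks per Mb correlated with protein-coding genes per Mb, counted per chromosome in the GRCm38.p6 table. Pearson r was 0.63 (permutation p = 0.0042, adjusted p = 0.0042) and Spearman rho was 0.75 (permutation p = 0.00038, adjusted p = 0.00038). In all, 12 coefficients were computed on overlapping sets of chromosomes, and p-values were adjusted separately for the Pearson and the Spearman coefficients. Without chromosomes 7 and 11, the 2 farthest from the median gene density, r was 0.67, and without chromosome 8 it was 0.80. Leaving out olfactory and vomeronasal receptor genes, which are numerous on chromosome 7 and silent in most tissues, r was 0.74 (permutation test, adjusted p = 0.00096), and 0.89 without chromosome 8. Chromosome 11, second in peak density, lay 1.21 residual SD above the line with all genes and 0.34 above the line without receptor genes.

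Chromosomes 7 and 8 lay more than 2 residual SD from this line, in opposite directions. Chromosome 7 lay −2.99 residual SD from it with all genes and −2.39 without receptor genes.

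Chromosome 8 had 3.36 peaks per Mb where the line through the other 18 autosomes gave 1.94 with all genes, 4.87 residual SD above it and 6.10 SD above it without receptor genes, so gene number does not account for the excess, and a few dense regions do not account for all of it, since its median 5 Mb bin held 14.5 peaks and no other autosome had a median as high. An extra copy of chromosome 8, a change known to arise in cultured mouse ES cells, is a candidate explanation: more control reads per base would leave fewer of its peaks at the scores set by the genome-wide background, and the odds ratio of such peaks was 0.12, with 3 of 159 peaks before the midpoint and 4 of 284 beyond it. Gene density does not explain that low share, which lay −3.88 residual SD from the line against it. Whether the share falls with peak density was not tested. Chromosome 11, with 3.18 peaks per Mb, had the next-lowest share among the autosomes (7.24%), whereas chromosome 19, with 2.79 per Mb, had 11.7%. The excess was uneven, 1.24 times the expected number up to the midpoint and 2.21 times beyond it. A gain of the whole chromosome does not predict this by itself, although 6 other autosomes were more uneven than its 1.79-fold. A gain of the distal part alone would leave a usual share of repeated scores before the midpoint. That share was 3 of 159 peaks, against at least 7.24% on each other autosome, which on this reading argues against such a gain. A gain that reaches both sides of the midpoint, or a higher occupancy of the distal part, stays open. The reading assumes that the repeated scores are those of a background-based q-value, which the sources do not state, and the read counts of the IgG and input libraries would decide it.

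The low density on X was not a matter of gene number, as X lay −3.34 residual SD from the line through the autosomes with all genes and −3.69 without receptor genes. J1 is known as a male line, and fewer reads per base on its single X may hold X peaks below the threshold. The odds ratio of peaks at the repeated scores was 2.02, in the direction this predicts, but with 40 peaks its interval includes 1, and Y, also a single copy, had 0 of 27 peaks at these scores, the opposite direction, with 26 of them in 2 stretches. The explanation therefore cannot be told apart from a lower occupancy of X. Of the 100 highest-scoring peaks 11 were on X (27.5% of its peaks against 1.93% of all peaks), a count made after 4 of the highest 10 were seen there. Of these, 7 lay in the stretch from 93130748 to 93152308, whose 8 peaks scored 29.9 to 432. The other 4 included the second-highest peak of the list.

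The grouping of peaks raises the question of repeated DNA. Mitochondrial DNA, present in many copies per cell, was covered to 72.2% by peaks. The stretch at the start of chromosome 9, the pair of high-scoring peaks of chromosome 2 and the 5964 bp peak of chromosome 17 may likewise stem from sequence that is present in more copies than the assembly shows, which was not tested for them singly. Regions this dense or strong do not account for the clustering as a whole. Without X, Y and the stretches with at least 8 peaks or a score of at least 100, 151 of the 161 stretches of at least 3 peaks were left. Random placement gave at most 11 and placement within 100 kb at most 65. The removal goes by peak number and score and not by copy number, so it cannot exclude repeated DNA in the stretches that were left. In the list as deposited, regional density on the scale of 100 kb does not account for all of the clustering either, as the excess over placement within 100 kb was 2.79 times. A larger peak broken into several by the caller stays open for part of it, since joining peaks under 500 bp apart lowered the number from 161 to 114. That was still above the highest value of 10 in random placement on the same chromosomes. The joined peaks were not placed within 100 kb, so whether they exceed regional density was not tested. Enhancer clusters remain an untested biological explanation.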
